A study of Homo sapiens with 3 samples.

How the data were processed

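Chromatin immunoprecipitation followed by sequencing was carried out with an antibody against total RNA polymerase II (Pol II) on H1299 cells. The series holds 3 libraries, namely Pol II from untreated cells, Pol II from cells transfected with miR-34a at 25 nM, and a pooled input without antibody. Each immunoprecipitation used 5 µl of antibody per the labels. Each group has 1 library, so no spread between replicates can be measured. The files used here are summary sheets of the peak calling and annotation. They hold no list of peaks by position and no values for single genes, so named genes, motifs and tracks were not analysed here. Values for the pooled input library itself were not analysed here.

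Per the submitters' processing notes, BWA, MACS2 and SICER were used, and no versions are given in the sources used here. Per the file headers and settings, the authors' intervals came from SICER, a caller that joins enriched windows into broad islands. The deposited settings name a window of 200 bp, a gap of 600 bp and a false discovery rate of 1e-10, and list the pooled input as control file of the peak calling settings. Peaks were called on each Pol II library separately, on build hg38 (NCBI build 38, GRCh38.p2 primary assembly). A larger gap or a looser rate joins more windows, so the number and the length of the intervals depend on these settings, and no second setting was among the sheets used here. The authors' signal was binned in steps of 32 bp with fragments set to 200 bp, per the file headers. The names the authors gave their tag sets contain the term uniqnorm, which the sheets do not explain.

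The authors' program merged overlapping intervals of both libraries into regions, with a largest gap of 0 bp, and counted regions by the library they contain. It counted intervals in a promoter window from 7500 bp upstream to 2500 bp downstream of a gene start, within 500 bp of a transcript start, within 200 bp of a CpG island, and within 10000 bp of a gene. The deposited share of intervals in each class is a fraction of the library's own intervals from 0 to 1, although its header carries a percent sign. Each such fraction equalled the class number divided by the interval number.

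The number of tags per library is not given in the sources used here. Mean signal per probe multiplied by the number of probes gave a total binned signal of 204143590 in each Pol II library, so the signal had been equalised between them before these summaries were made. Probes were taken as 32-bp bins with signal, because their number was below the number of bins in the listed chromosomes. If a fragment fills between 6.25 and 8 bins, this total stands for 25500000 to 32700000 fragments per library. That range is an estimate and no interval was derived from it.

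From these sheets the following were computed with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and drawn with Matplotlib 3.10.9. Covered length was the number of intervals times their mean length. Length covered in both libraries was the sum of both covered lengths minus the length of the merged regions, after adding 1 bp per merged region, because merged lengths were given as end minus start. Merged regions with 2 intervals hold 1 of each library, because intervals of 1 library do not overlap each other, and the intervals left in larger regions followed by subtraction. Genes without a CpG island promoter were all genes with a promoter interval minus those with a CpG island.

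Ratios of numbers carry exact conditional binomial intervals and shares carry exact Clopper-Pearson intervals, both at 95%. Differences of shares carry Newcombe intervals. Classes and single chromosomes were compared with two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 4 classes or 24 chromosomes, and the spread over chromosomes with a chi-square statistic and 100000 resamples with fixed margins. These tests compare 2 libraries, not 2 conditions, and cover counting error only. Intervals of both libraries lie largely in the same regions and are not independent draws, so these tests lean towards finding no difference. The 95% intervals of ratios also take the numbers of the libraries as independent counts. They are approximate where both libraries count the same regions or genes. The overlap arithmetic was tested on simulated interval sets and returned the known lengths. In 100 simulated tables of 24 chromosomes with no change the chi-square test called 2. In 100 tables with 1 chromosome changed by 1.5-fold it called 100. Those tables held independent draws with shares set by chromosome length. They do not show whether a change as small as the largest ratio of shares seen, 1.16 for chromosome 13, would be called.

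No p-value is given between conditions. The chromosomes named were those with the 3 highest and the 3 lowest ratios of shares, plus X and Y, by a rule written before the data were examined, which also held lists of miR-34a targets, p53 pathway, histone, immediate early, interferon, transcription and housekeeping genes. Chromosomes 4, 17, 19 and 21 were named as well, chosen after their values were seen. Numbers of genes found in 1 library only were derived by subtraction from the gene counts of merged regions and then left out, because the promoter counts of merged regions are too low to hold the intervals of the libraries. The gene lists gave no result, because no sheet used here names genes. The mitochondrial chromosome, the share of tags in peaks, mapping and duplicate rates, and correlation coefficients of signal were planned and are not analysed here. The alternatives tried were other units of counting (regions, covered length), other denominators, and other sets of chromosomes. Their effect is in the closing section.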

Results

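RNA polymerase II occupancy was profiled by ChIP-seq in NCI-H1299 cells, a line from a non-small cell lung carcinoma, with and without transfection of miR-34a. MiR-34a is a microRNA that p53 induces and that represses many genes of cell cycle entry. H1299 cells do not make p53. The design asks how transfection of the microRNA alters where Pol II sits on the genome. The comparison library came from cells labelled with no treatment. No library from cells given a control RNA or the transfection alone is in the series. Effects of the microRNA therefore cannot be told apart from those of transfection. There was 1 Pol II library from untreated cells, 1 from cells given 25 nM miR-34a, and 1 pooled input. The total binned signal was 204143590 in each Pol II library, a total that had been equalised, and the number of tags behind it is not given in the sources used here. Without replicates, every interval given here covers counting error only, and every difference is one between 2 libraries.

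Called Pol II intervals were fewer but longer in the miR-34a library. SICER called 17516 intervals in untreated cells and 16589 after miR-34a, a ratio of 0.947 (95% interval 0.927 to 0.967). The mean interval was 15.2 kb long in the untreated library and 18.1 kb in the miR-34a library, a ratio of 1.19. The length covered by Pol II intervals was 266.6 Mb, or 8.63% of the listed chromosomes, in untreated cells. It was 300.9 Mb, or 9.74%, after miR-34a, which is 12.9% more. The longest interval was 393.6 kb without and 395 kb with the microRNA. The number of merged regions that held an interval went the other way from the number of intervals. It was 14105 for untreated cells and 14446 for miR-34a (ratio 1.02, 95% interval 1.001 to 1.05). Both numbers include the same 11908 shared regions, so this interval, which takes them as independent counts, is approximate.

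Signal reached more bins in the miR-34a library. Signal was present in 55380912 bins of the untreated library and in 59657592 of the miR-34a library, which is 57.4% and 61.8% of all bins if each probe is a 32-bp bin. Mean signal in these bins was 3.69 in untreated cells and 3.42 after miR-34a, a ratio of 0.928, which the equalised total fixes as the inverse of the ratio of bin numbers. The highest single bin held 353 in the untreated library and 297 in the miR-34a library, a ratio of 0.841. Called intervals covered 8.63% and 9.74% of the chromosomes, so most of these bins lay outside intervals, and Pol II signal and background are not separated in these values. No error can be attached to them.

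**Figure D1:**
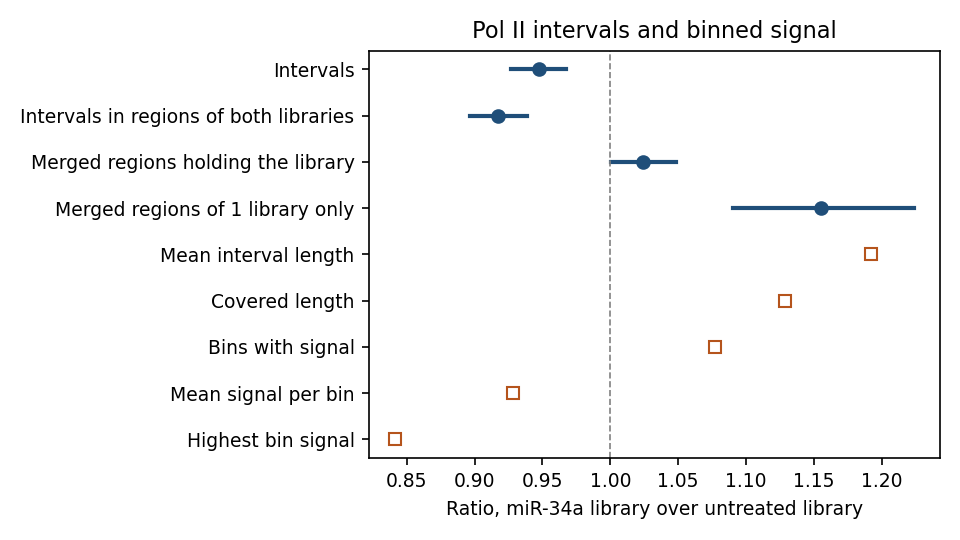
Each row gives the ratio of the miR-34a library to the untreated library on a linear axis, with a dashed line at 1; filled circles are ratios of numbers with exact 95% intervals for counting error, and open squares are ratios of lengths or signal, which have no interval. Intervals lie below 1 at 0.947, while covered length lies above it at 1.13.

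Most Pol II regions were found in both libraries. Of 16643 merged regions, 11908 (71.5%) held intervals of both, 2197 (13.2%) held untreated intervals only and 2538 (15.2%) held miR-34a intervals only. Regions seen in 1 library only were more numerous on the miR-34a side (ratio 1.16, 95% interval 1.09 to 1.22). Of the untreated intervals, 87.5% (95% interval 87.0 to 87.9) lay in a region that also held a miR-34a interval. Of the miR-34a intervals, 84.7% (95% interval 84.1 to 85.2) lay in a region that also held an untreated one. By length, 232.2 Mb was covered in both libraries, 34.4 Mb in the untreated library only and 68.7 Mb in the miR-34a library only. Thus 87.1% of the length covered in the untreated library was also covered in the miR-34a library. In reverse, 77.2% of the length covered in the miR-34a library was also covered in the untreated library.

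The shared regions differed in how they were divided. In 8860 of them each library had 1 interval. The remaining 3048 shared regions (25.6%) held 3 or more intervals, up to 16, and these contained 6459 untreated and 5191 miR-34a intervals. That is 2.12 intervals per region in untreated cells and 1.70 after miR-34a (ratio of numbers 0.804, 95% interval 0.775 to 0.834). All shared regions together held 15319 untreated and 14051 miR-34a intervals, a difference of -1268, against a difference of -927 over all intervals. A shared region with 2 intervals holds 1 of each library by construction, so the whole difference in shared regions falls in those with 3 or more. The ratio of 0.804 thus restates the difference of -1268 over fewer intervals and is no further evidence. Its 95% interval takes intervals of the same region as independent counts and is approximate.

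**Figure D2:**
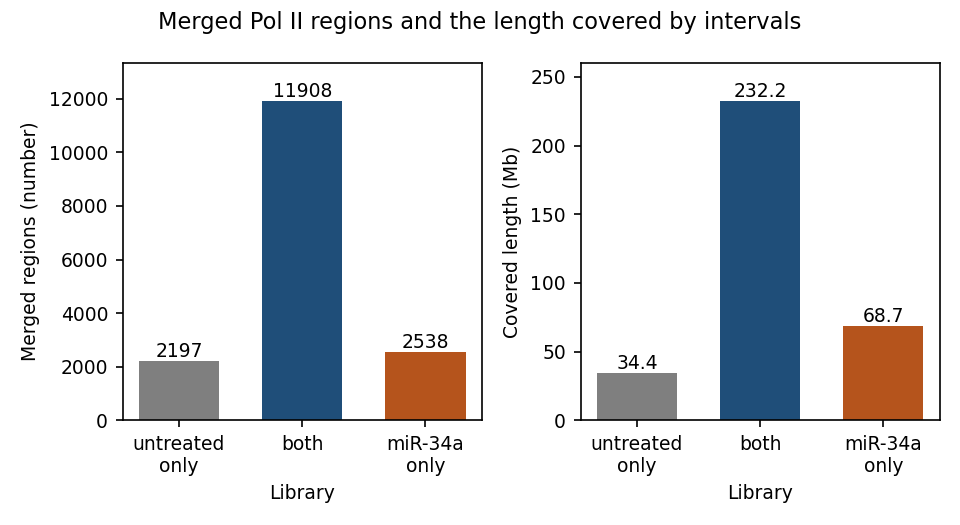
Bars give the number of merged Pol II regions (left) and the length covered by intervals in Mb (right) found in the untreated library only, in both, or in the miR-34a library only, with axes from 0. The 2 libraries share 11908 regions, and the length covered in the miR-34a library only is 68.7 Mb against 34.4 Mb in the untreated library only.

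Most Pol II intervals of both libraries lay near genes and CpG islands, the GC-rich stretches at which many broadly expressed genes start. The shares that intervals placed at random would give were not computed. Within 10 kb of a gene lay 97.5% of untreated and 97.7% of miR-34a intervals. The promoter window held 54.2% of untreated intervals (95% interval 53.4 to 54.9) and 53.7% after miR-34a (52.9 to 54.5). Transcript starts had 41.3% (40.6 to 42.1) of untreated and 40.4% (39.6 to 41.1) of miR-34a intervals within 500 bp. CpG islands had 57.6% (56.9 to 58.3) and 56.5% (55.8 to 57.3) within 200 bp. None of these shares passed Fisher's exact test between the libraries after adjustment. The adjusted p was 0.37 for the promoter window, 0.17 for transcript starts, 0.17 for CpG islands and 0.24 for intervals beyond 10 kb of any gene. The difference in share, miR-34a minus untreated, was -0.49 percentage points for the promoter window (95% interval -1.54 to 0.57), -0.92 for transcript starts (-1.97 to 0.12) and -1.06 for CpG islands (-2.11 to -0.01). A second summary by the same program counts 20718 intervals near promoters (60.7% of 34105) where the library summaries add up to 18399 (53.9%), so the level of the promoter share depends on which count is read. The rule behind each count is not given, and mean interval length differed between the libraries. A difference in promoter or start share is therefore not a measure of Pol II placement alone.

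Genes whose promoters carry a CpG island and genes whose promoters do not had ratios on either side of 1. Genes with a Pol II interval in the promoter window numbered 19403 in untreated cells and 18912 after miR-34a (ratio 0.975, 95% interval 0.955 to 0.994). Those with a CpG island in the promoter numbered 15703 and 15060 (ratio 0.959, 0.938 to 0.981). Those without one numbered 3700 and 3852 (ratio 1.04, 0.995 to 1.09). A gene can count in both libraries, so these intervals, which take the numbers as independent, are approximate. The class without a CpG island made up 19.1% of the genes in the untreated library (95% interval 18.5 to 19.6) and 20.4% in the miR-34a library (19.8 to 20.9), with p = 0.0014 in a two-sided Fisher's exact test between the libraries. Neighbouring genes can share an interval, which makes this p too small, and most intervals of the libraries lie in shared regions, which makes it too large, so it is a guide only.

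Over a wider margin, 20334 genes of the untreated library and 19781 of the miR-34a library had an interval within 10 kb (ratio 0.973, 95% interval 0.954 to 0.992). The miR-34a library therefore covered more sequence and had fewer annotated genes counted within 10 kb of an interval. The gene ratio was above the ratio of interval numbers, which was 0.947. The share of intervals within 10 kb of a gene was 97.5% in the untreated and 97.7% in the miR-34a library. These counts therefore do not place the added length away from genes, and the rule behind the gene numbers is not given.

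**Figure D3:**
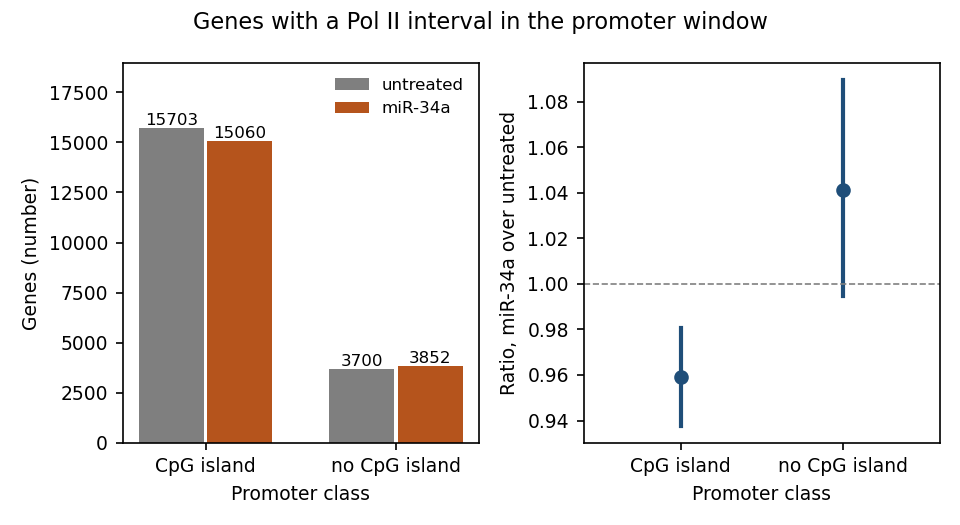
The left panel gives numbers of genes with a Pol II interval in the promoter window for each library, by whether the promoter carries a CpG island, with bars from 0; the right panel gives the ratio of miR-34a over untreated with exact 95% intervals for counting error and a dashed line at 1. The ratio is 0.959 for CpG island genes and 1.04 for the others, whose interval includes 1. These intervals take the gene numbers of the libraries as independent and are approximate.

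Pol II intervals followed gene density across chromosomes in both libraries. Chromosome 19, the most gene-dense, had 15.1 intervals per Mb in untreated cells and 14.5 after miR-34a, and chromosome 17 had 12.2 and 11.7. Chromosome 4 had 3.45 and 3.36, and chromosome 13 had 3.40 and 3.72. Across the 23 chromosomes with at least 100 intervals, intervals per Mb and genes per Mb correlated with Pearson's r = 0.960 and Spearman's rho = 0.918 in the untreated library, and with r = 0.956 and rho = 0.900 in the miR-34a library. The permutation p of each was 1e-05, the smallest that 100000 resamples can give. Without chromosomes 17 and 19, which lay farthest from the median gene density, r was 0.890 and 0.854. Chromosomes are not independent replicates.

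The miR-34a library had fewer intervals than the untreated one on 21 of 24 chromosomes, an equal number on Y, and more on chromosomes 13 and X. Chromosome 13 had 389 untreated and 426 miR-34a intervals, and its share of all intervals had a ratio of 1.16 (95% interval 1.01 to 1.33). The X chromosome had 625 and 659 (ratio of shares 1.11, 0.996 to 1.24). Chromosome Y had 1 interval in each library, which gives no usable ratio (1.06, with an interval from 0.013 to 82.9). The lowest ratios of shares were 0.915 for chromosome 20 (0.801 to 1.04), 0.941 for chromosome 7 (0.855 to 1.04) and 0.946 for chromosome 9 (0.846 to 1.06). The spread over chromosomes was no larger than that of independently drawn intervals, with a chi-square p of 0.86 from resampling. Most intervals of the libraries lie in shared regions, so differences vary less than this test assumes and it leans towards finding none. Chromosome 13 had an unadjusted p of 0.036 in Fisher's exact test, and the smallest adjusted p over 24 chromosomes was 0.64.

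**Figure D4:**
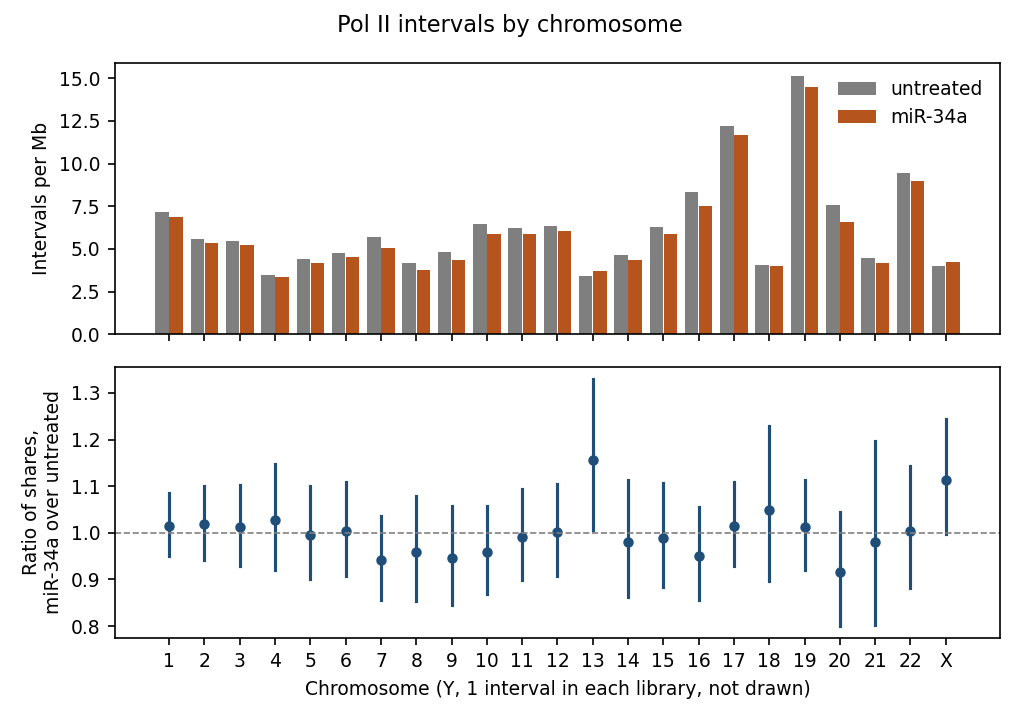
The upper panel gives Pol II intervals per Mb for each chromosome and library, with bars from 0; the lower panel gives the ratio of each chromosome's share of intervals, miR-34a over untreated, with exact 95% intervals for counting error and a dashed line at 1. Chromosome 19 has the highest density, and chromosomes 13 and X have the highest ratios of those drawn, at 1.16 and 1.11.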

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

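The total-signal alternative, the shares counted by merged regions and the chromosome sets were fixed before the data were examined. All other alternatives, including every one that turned a direction, were chosen after. The lower number of intervals in the miR-34a library (ratio 0.947) depended on what was counted. The ratio was 1.02 for regions holding the library's intervals, 1.13 for covered length and 1.16 for regions of 1 library only, so the direction turned. Both region ratios rest on the same difference of 341 regions and are not separate reversals. Covered length is a different measure, which also depends on interval length. For intervals in regions of both libraries the ratio was 0.917. The total signal is equal by construction and leaves the ratio as it is. Per occupied bin the ratio was 0.879. The share of untreated intervals found again after miR-34a was 84.4% when regions were counted in place of intervals. The reverse share was 82.4% by regions and 77.2% by covered length. The chi-square p over chromosomes was 0.94 without X and Y and 0.82 with only chromosomes of at least 100 intervals, so it stayed above 0.05. The latter set leaves out only chromosome Y, with 1 interval in each library, so its outcome was all but fixed in advance. As shares of the library's intervals, the ratios were 0.991 for the promoter window, 0.978 for transcript starts, 0.982 for CpG islands and 0.910 beyond 10 kb of any gene. Per Mb covered they were 0.832, 0.820, 0.824 and 0.763, which could only fall below the ratios of numbers, because covered length was larger after miR-34a. Relative to all genes with a promoter interval, the ratio was 0.984 for CpG island genes and 1.07 for the others. The ratio of shares of chromosome 13 was 1.16 without X and Y. It was also 1.16, and that of X was 1.11, with only chromosomes of at least 100 intervals, where leaving out Y could hardly change them. The share of untreated length covered again was 87.1%, and the promoter share over both libraries was 60.7% in the second summary. A stricter peak threshold, a second caller, other tag denominators, and chromosome shares over the pooled input were planned and not run, because the sheets used here do not hold those values. Leaving out a replicate was not possible with 1 library per group. Counting error limits single chromosomes, as for chromosome 21, whose interval runs from 0.802 to 1.20.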

Other observations

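All tests of explanations below were chosen after the results were seen. The relation between gene density and the ratio of interval numbers was tested over chromosomes, although the spread of that ratio was no larger than that of independently drawn intervals. Across 23 chromosomes the log2 ratio of miR-34a over untreated intervals correlated with genes per Mb with Pearson's r = -0.20 (permutation p = 0.32, adjusted p = 0.43 over 2 relations) and Spearman's rho = -0.37 (p = 0.080, adjusted p = 0.080). With CpG islands per Mb the values were r = -0.14 (p = 0.43, adjusted p = 0.43) and rho = -0.47 (p = 0.025, adjusted p = 0.0497). Without chromosomes 17 and 19, the 2 densest, r with genes per Mb was -0.58 (p = 0.0052, adjusted p = 0.0097 over 2 relations) and rho was -0.52 (p = 0.016, adjusted p = 0.016). With CpG islands per Mb and the same 2 left out, r was -0.57 (p = 0.0097, adjusted p = 0.0097) and rho was -0.65 (p = 0.0020, adjusted p = 0.0040). The adjustment does not cover the choice to leave out chromosomes. A higher ratio on gene-poor chromosomes is a hypothesis that stays open. For genes per Mb it passes 0.05 only without those 2 chromosomes, and for CpG islands per Mb rho passes it also with them.

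Fewer and longer intervals in the miR-34a library are the pattern to look at first. Regions of 1 library only had a ratio of 1.16 (95% interval 1.09 to 1.22), miR-34a over untreated. These numbers show no net loss of whole regions from the miR-34a library. Longer miR-34a intervals can also touch more untreated ones, which lowers the number of untreated-only regions and raises that ratio. The ratio therefore cannot decide whether whole regions were lost. Loss at some regions stays open, because 2197 regions held untreated intervals only. Whether intervals of shared regions were joined after miR-34a or are split in the untreated library cannot be read from these counts. A different number of tags stays open, because the ratio of total binned signal, which was 1, had been set by equalising and does not show the depth sequenced. A flatter signal from lower enrichment may also contribute, because the number of bins with signal had a ratio of 1.08, and it cannot be told apart from a wider spread of Pol II along genes, since the share of tags in intervals was not analysed here and each condition has 1 library.

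The ratios of CpG island genes and other genes on either side of 1 are the second pattern. If promoters are counted by overlap, wider intervals alone would reach more of them in both classes. The ratio of 0.959 (95% interval 0.938 to 0.981) for CpG island genes goes against that. The rule behind the gene numbers is not given, however, and promoter numbers of merged regions did not follow overlap. This test therefore cannot decide on wider intervals as the cause. For the genes without a CpG island, whose ratio was 1.04 (0.995 to 1.09), a gain through wider intervals cannot be told apart from new occupancy, because the genes themselves are not listed. An effect of miR-34a on either class stays open and untested, as the microRNA, the transfection and the library are confounded.

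The third pattern is in the summary itself. The library summary places 1492 merged regions within 500 bp of a transcript start and 5899 in the promoter window. The start intervals of the libraries need at least 4558 regions to hold them, and the promoter intervals at least 6765, once the surplus of intervals over regions (3411 untreated, 2143 miR-34a) is taken off. Counting by overlap is therefore argued against for merged regions, and the program's other summary gives 10070 regions near promoters. Counts for CpG islands were equal in both summaries, at 19470 intervals and 9550 regions. The rule behind the lower numbers was not tested, so the promoter and start numbers of merged regions are best left out of comparisons with those of single libraries. Whether the same rule affects the numbers of single libraries, whose mean interval lengths differ, was not tested either.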
